A study of Mus musculus with 8 samples.

How the data were processed

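The series holds 8 arrays of mouse embryos (strain C57BL/6, embryonic day 10.5): neural tube and paraxial tissue of 2 wild-type and 2 mutant embryos. Per the labels' protocols, RNA was isolated from laser-captured material with the PicoPure kit, and cDNA was labelled chemically with Cy5 by the Kreatech ULS kit. Labels give the embryo of each sample, so both tissues of an embryo were matched and each embryo is 1 replicate of its genotype. Per the file headers and the submitters' processing notes, the intensities were extracted with Agilent Feature Extraction 11.0.1.1 under a red-channel protocol with spatial detrending, multiplicative detrending and surrogate values on, and the array design was annotated on mouse build mm9. The deposited intensity values are linear processed signals of the red channel, 1 file per array and not pooled. The authors' value table of the whole series holds the same intensities, without centring between arrays and on a linear scale, differing from the scanner files by at most 0.497% (rounding), and was used as an alternative. All 8 arrays lay on 1 slide and 1 scan, with the replicate 1 arrays in row 1 and the replicate 2 arrays in row 2.

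Each array had 62976 spots, of which 3671 control spots were left out. Spots marked as outliers by the scanner software were left out and the remaining spots of a probe averaged, giving 55664 of 55681 probes (17 had every spot marked on an array). No spot was saturated. The processed signal was scaled by taking log2 and subtracting the 75th percentile of each array, with a common constant added back. Probes were kept if they were well above background on both arrays of at least 1 group, which left 42754 probes. Probes were named through a table of RefSeq accessions and symbols: 26045 by accession and 3200 by symbol, while 26419 kept the name in the files. The brightest kept probe stood for each of 28940 genes, 7939 of which had more than 1 probe. The reference table carried no mm9 annotation, so no exon or untranslated region is given for a probe.

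Comparisons were made with limma 3.58.1 in R 4.3.3, with files read by the data.table package (version 1.17.8). A model of 4 group means was fitted to all 8 arrays with the embryo as a random block (duplicateCorrelation; consensus correlation 0.603, 4 residual and 2.93 prior degrees of freedom), followed by eBayes and Benjamini-Hochberg adjustment at 0.05. The contrasts were mutant minus wild type in each tissue, their mean and difference, and neural tube minus paraxial tissue in each genotype and on average. Standard errors are those of this model, and limma p-values rest on 2 embryos per genotype. Where a gene was not well above background on any array of a group, the change is given as "at least" a fold: the mean of the brighter group over a floor set, per array, at the higher of the gene's own value and the lowest signal well above background, both on the scaled log2 scale.

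In all, 36 gene lists (markers of cell types in and around both tissues, signalling targets, cell cycle, chromatin and stress genes) were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01 on the moderated statistics, adjusted over 252 tests (36 lists by 7 contrasts). They were tested again with a correlation estimated from the arrays and with fry. That estimate rests on 4 residual degrees of freedom. It can fall below 0.01, and for such a list the second test is looser than the first. At the preset correlation camera compares members with the other genes, so its p-value measures the spread across genes and not that between embryos. By the rule, the named genes of a contrast are Gmnn, the 10 genes per direction (5 for the interaction) with the largest change among those that passed and whose groups did not overlap, filled up by smallest unadjusted p, and up to 4 members with the smallest p in each list described. Genes outside it (the Y-linked genes, Xist, the 5 brightest surface ectoderm genes and members named under an alternative) were chosen after their values were seen.

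Both tissues of an embryo deviated together from their group means (r across genes 0.562 in wild type and 0.607 in mutants), and the labels give the shared embryo. Numbers were not taken to pair a wild-type with a mutant embryo. The same code was tested on simulated arrays of 28940 independent genes in which 50 genes per size were changed, with no effect of slide row or brightness. In paraxial tissue 34% of changes of 2 and 92% of changes of 3 (log2) were recovered with 9 false calls. For the tissue difference in wild type, 26% of changes of 1 and 96% of changes of 2 were recovered with 12 false calls. A list shifted by 0.5 was called in neural tube (adjusted p = 4.37e-09) with 0 other lists called, on genes simulated as independent.

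Alternatives were quantile, median and cyclic loess scaling, normexp background correction (offset 50), the authors' value table, other probe filters and probe summaries, trend and robust moderation, array weights, other blocks, fits to 4 arrays, a fold threshold of 2 with unadjusted p, and leaving out each array or embryo. Cyclic loess and left-out embryos for gene lists were added after seeing the data. A left-out fit leaves 1 array in a group, which is then assumed to vary like the other groups, and keeps the embryo correlation of the 8 arrays. A gene that the naming rule picked is not reported here.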

Results

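Geminin, encoded by Gmnn, is a small protein that binds the replication licensing factor Cdt1 and also contacts chromatin regulators. The series asked how the conditional loss of Geminin changed transcript levels in the spinal neural tube, the epithelium that forms the spinal cord, and in the neighbouring paraxial tissue, which forms somites, vertebrae and muscle. Each tissue was cut out on its own with a laser from wild-type and from mutant mouse embryos at E10.5, and RNA from each was measured on a 1-colour Agilent array. There were 4 groups (wild-type neural tube, mutant neural tube, wild-type paraxial tissue and mutant paraxial tissue) with 2 arrays in each, from 2 wild-type and 2 mutant embryos, and each embryo gave both tissues. Between 71.5% and 77.9% of probes were well above background on an array, and the 75th percentile of the processed signal ran from 3164 to 6361. The median signal was 2.11 to 3.16 times that of negative control spots. In each tissue both mutant arrays had a lower share of such probes, and a lower such ratio, than both wild-type arrays. The share in neural tube was 73.5% and 74.0% in mutants against 77.6% and 77.9% in wild type. In paraxial tissue it was 71.5% and 73.1% against 77.4% and 73.6%. With 2 embryos per genotype, the number of arrays limits the precision of every comparison, and 28940 genes were tested in each.

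Gmnn, the targeted gene, stood lower in mutants in both tissues, and neither difference passed the test. It was read by 1 probe, at chromosome 13 from 24843715 to 24843774 on mouse build mm9. Its scaled log2 signal in neural tube was 12.30 ± 0.08 (SD, n = 2) in wild type and 11.95 ± 0.22 in mutants, a difference of -0.35 ± 0.25 (SE; limma adjusted p = 0.921). In paraxial tissue it was 12.04 ± 0.23 in wild type and 11.41 ± 0.02 in mutants, a difference of -0.63 ± 0.25 (SE; limma adjusted p = 0.995). All 4 mutant values lay below both wild-type values of their tissue. The labels name neither the cre driver nor the deleted part of the gene, and a probe outside that part would check nothing about the genotype labels.

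The first comparison, neural tube against paraxial tissue within wild-type embryos, describes what was captured. Neural tube carried more of the genes of the ventral neural tube and floor plate, and paraxial tissue carried more of the genes of muscle, sclerotome and extracellular matrix. In all, 709 of 28940 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 222 were higher and 487 lower in neural tube. Of the 26 measured ventral neural tube and floor plate genes, 9 were higher over all genes and 22 when adjusted over the list alone, with a median log2 difference of 1.72 (camera adjusted p = 4.27e-25). Among them, Nkx2-2, a ventral progenitor transcription factor, was higher by 2.53 ± 0.21 (log2, SE; adjusted p = 0.00716), the floor plate signal Shh by 2.13 ± 0.19 (adjusted p = 0.00965), and Nkx6-1 by 2.40 ± 0.29 (adjusted p = 0.0154). Foxa2, a floor plate and notochord transcription factor, was higher by 4.80 ± 0.44 (adjusted p = 0.00965) and was well above background on 1 of the 2 wild-type paraxial arrays. The size of the Foxa2 difference is therefore uncertain, and it ran from 1.96 to 5.42 over the alternatives. The motor neuron determinants Olig2 and Mnx1 were higher by 3.21 ± 0.54 on the log2 scale and by at least 9.56-fold, respectively.

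Of 34 measured dermomyotome and myotome genes, 23 were lower in wild-type neural tube over all genes and 27 adjusted over the list alone (median -2.70; camera adjusted p = 2.99e-55). The muscle filament gene Des differed by -4.13 ± 0.32, the troponin Tnnc2 by -3.30 ± 0.26 and the myosin light chains Myl4 and Myl1 by -3.51 ± 0.28 and -4.73 ± 0.39, all with an adjusted p of 0.00716 or 0.00727. Titin (Ttn) differed by -5.47 ± 0.58 and the cardiac and embryonic troponin Tnnt2 by -5.26 ± 0.64, and the sarcoplasmic reticulum regulator Sln was lower by at least 11.9-fold. Of 24 sclerotome and mesenchyme genes, 8 were lower over all genes and 18 adjusted over the list alone (median -2.14; camera adjusted p = 5.19e-22), among them Foxc2 (-2.10 ± 0.21), Tgfbi (-2.17 ± 0.21), Twist1 (-3.05 ± 0.33) and Twist2 (-3.24 ± 0.33). Of 35 extracellular matrix genes, 10 were lower over all genes and 27 adjusted over the list alone (median -0.99; camera adjusted p = 6.85e-24), such as the collagens Col1a1 (-2.14 ± 0.15), Col1a2 (-1.51 ± 0.16) and Col6a1 (-1.85 ± 0.22).

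Neural progenitor genes were also higher in wild-type neural tube (19 measured, 1 higher over all genes and 13 over the list alone, median 0.70; camera adjusted p = 1.50e-06), led by Fzd3 at 0.80 ± 0.15. Within the same list the progenitor factors Pax6 and Rfx4 stood at 2.05 ± 0.43 and 2.18 ± 0.44 and did not pass over all genes (adjusted p = 0.0619 and 0.0573). Hox paralogs 1 to 5 were higher (15 measured, 3 over all genes and 7 over the list alone, median 0.57; camera adjusted p = 2.00e-05), with Hoxb1 higher by at least 6.24-fold, Hoxd3 by 1.15 ± 0.21 and Hoxb2 by 1.15 ± 0.22. Those 6 lists held with an estimated correlation. The camera adjusted p was then 9.05e-30 for ventral genes, 4.12e-08 for muscle and 6.13e-04 for sclerotome. It was 0.00723 for matrix, 0.0222 for progenitors and 4.04e-05 for Hox paralogs 1 to 5. For ventral genes it was smaller than at the preset correlation, so there it is no stricter check. Differentiated neuron genes had a median difference of 1.06 (camera adjusted p = 1.47e-06), a call that was lost at adjusted p = 0.368 with an estimated correlation. The count of 709 genes fell to 69, 111 and 40 without wild-type neural tube 1, wild-type neural tube 2 or wild-type paraxial tissue 2, respectively, and to 90 and 31 without both arrays of wild-type embryo 1 or 2. It was 181 without either mutant embryo, 4 without the embryo in the model and 51 with the embryo as a fixed term.

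**Figure D1:**
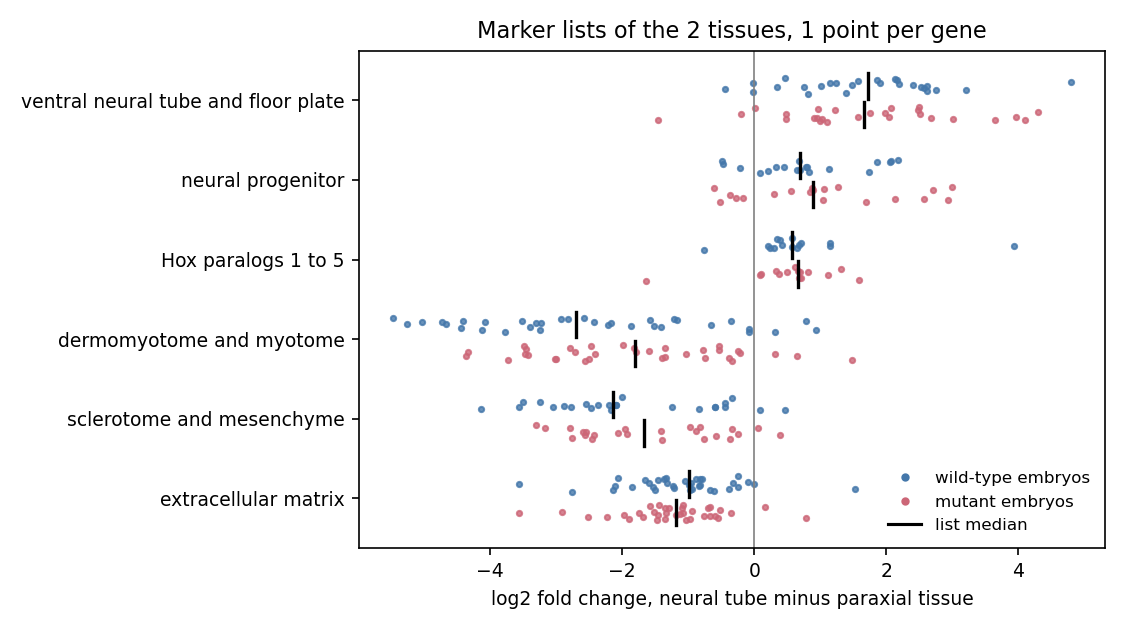
Log2 fold change of neural tube over paraxial tissue for each measured gene of 6 marker lists (points), in wild-type (blue) and mutant (red) embryos, with the list median as a black bar. In wild type the medians are 1.72 for ventral neural tube genes, -2.70 for dermomyotome and myotome genes and -2.14 for sclerotome genes.

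In mutant embryos the same comparison gave 1694 genes, 776 higher and 918 lower in neural tube. Ventral neural tube genes were again higher (15 of 26 over all genes and 20 over the list alone, median 1.66; camera adjusted p = 2.69e-22), including Nkx6-2 by at least 7.43-fold. The progenitor transcription factor Dbx2, of the same list, was higher by 4.30 ± 0.69 (adjusted p = 0.0203). Dermomyotome and myotome genes were lower (18 of 34 over all genes and 23 over the list alone, median -1.81; camera adjusted p = 1.21e-23). Endothelial genes were lower in mutant neural tube than in mutant paraxial tissue (25 measured, 9 over all genes and 23 over the list alone, median -1.14; camera adjusted p = 4.06e-14, and 0.0250 with an estimated correlation), led by the transcription factor Erg (-2.10 ± 0.27) and Plvap (-1.50 ± 0.21). So were erythroid genes (17 measured, 7 over all genes and 13 over the list alone, median -0.95; camera adjusted p = 3.82e-12, and 3.11e-11 with an estimated correlation), led by Alas2, the first enzyme of erythroid haem synthesis (-1.23 ± 0.14), and the red cell anion exchanger Slc4a1 (-1.37 ± 0.18). The count fell to 233, 437, 78 and 86 without mutant neural tube 1, mutant paraxial tissue 1, mutant neural tube 2 and mutant paraxial tissue 2, to 32 and 0 without both arrays of mutant embryo 1 or 2, and to 1102 without either wild-type embryo. Without the embryo in the model it was 0 in limma (2859 genes at an unadjusted p under 0.05), and 211 with the embryo as a fixed term. Averaged over genotypes, 3459 genes differed between tissues, 1720 higher and 1739 lower in neural tube (49.7% higher), and with normexp background correction the split was 1635 to 2506 (39.5% higher). The averaged count was 2305, 1861, 1508, 1839 and 1906 without mutant paraxial tissue 1, wild-type neural tube 2, wild-type paraxial tissue 2, mutant neural tube 2 and mutant paraxial tissue 2, and 1470, 1007 and 794 without mutant embryo 1, wild-type embryo 2 and mutant embryo 2.

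Mutant paraxial tissue, compared with wild-type paraxial tissue, had higher levels of p53 target genes and of surface ectoderm and epithelial genes. Of 36 measured p53 targets, 33 lay higher in mutants, with a median log2 change of 0.53 (camera adjusted p = 7.86e-17, and 7.74e-07 with an estimated correlation). Adjusted over the list alone, 4 rose, and over all genes 0. The 4 were Eda2r, a member of the TNF receptor family (2.65 ± 0.38, SE), cyclin G1 (Ccng1, 2.40 ± 0.36), the pro-apoptotic BH3-only gene Pmaip1 (1.99 ± 0.38) and Dcxr (1.39 ± 0.29). The mean of the list relative to its mean over all arrays was 0.64 and 0.31 in the mutant paraxial arrays and -0.30 and -0.17 in the wild-type ones. Markers of surface ectoderm, with a mean of 0.92 and 0.53 on the same mutant arrays and -0.46 and -0.14 on the wild-type ones, moved with them.

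Of 22 surface ectoderm and epithelial genes, 21 lay higher in mutant paraxial tissue (median 0.97; camera adjusted p = 1.58e-15, and 5.36e-06 with an estimated correlation). Adjusted over the list alone 9 rose, and over all genes 0. Members with the smallest p were the simple-epithelium keratins Krt8 (2.47 ± 0.61) and Krt18 (2.13 ± 0.48), the adhesion molecule Epcam (1.74 ± 0.43) and the tight junction gene Cldn6 (2.62 ± 0.70). Erythroid genes were also higher (12 of 17, median 0.53; camera adjusted p = 4.27e-06, and 2.51e-05 with an estimated correlation), 2 of them rising when adjusted over the list alone. Alas2 stood at 0.90 ± 0.23 and the embryonic globin Hbb-y at 0.98 ± 0.24, although only 1 of the 2 probes of Hbb-y had this sign. Gut and notochord genes were higher (11 of 13, median 0.69; camera adjusted p = 7.93e-05, and 8.93e-05 with an estimated correlation), with 0 members passing alone, Krt19 at 1.86 ± 0.54 and Gata6 at 2.14 ± 0.70. Krt19 is also a member of the surface ectoderm list. Foxa2 and Shh, likewise among the gut and notochord members with the smallest p, belong to the ventral neural tube and floor plate list too.

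Targets of BMP and TGF-beta signalling were higher in mutant paraxial tissue (13 of 15, median 0.66; camera adjusted p = 3.81e-04, and 0.00137 with an estimated correlation), with Id1 at 0.96 ± 0.30 and Id2 at 0.96 ± 0.44. Genes of the retinoic acid pathway were higher too (14 of 18, median 0.27; camera adjusted p = 0.00658, and 0.00723 with an estimated correlation), among them the retinoic acid-degrading enzyme Cyp26b1 (1.57 ± 0.43) and the synthesising enzyme Aldh1a2 (1.40 ± 0.44). None of the members of these 2 lists passed, over all genes or adjusted over the list alone. Without wild-type paraxial array 2 the adjusted p was 0.0597 for the BMP list and 0.0780 for the retinoic acid list. By fry the BMP list was lost (adjusted p = 0.0544).

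Muscle genes lay the other way. Of 34 dermomyotome and myotome genes, 28 lay lower in mutant paraxial tissue (median -1.01, camera adjusted p = 6.64e-10), a call lost at adjusted p = 0.0592 with an estimated correlation. The muscle median ran from -1.33 to -0.60 over the left-out fits. The acetylcholine receptor subunit Chrnd stood at -1.49 ± 0.45, the muscle progenitor factor Pax7 at -1.64 ± 0.54 and the muscle caveolin Cav3 at least 2.11-fold lower, and 0 members passed over all genes or the list alone. Differentiated neuron genes lay lower as well (25 of 30, median -0.92; camera adjusted p = 1.21e-07, but adjusted p = 0.315 with an estimated correlation, and 0.0835 with the preset one without wild-type embryo 1, where the median was -0.12), led by Robo3 (-3.60 ± 1.29) and Stmn4 (-1.23 ± 0.47). The neuron list mean was 0.50 on wild-type paraxial array 1, against -0.69 on wild-type array 2 and -1.05 and -0.92 on the mutant arrays. Endothelial genes lay higher (24 of 25, median 0.63, camera adjusted p = 1.25e-05, but adjusted p = 0.253 with an estimated correlation). Plvap stood at 0.78 ± 0.33 and Erg at 0.97 ± 0.43. Over the fits that left out an array or embryo, the endothelial median ran from 0.27 to 0.87.

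No single gene passed in paraxial tissue. limma called 0 of 28940 genes, with 971 at an unadjusted p under 0.05, fewer than the 1447 expected by chance. With trend and robust moderation it called 0 (950 unadjusted) and without an embryo block 0 (1160). Apart from p53 targets, the genes with the smallest p on the higher side included Ahnak2 (2.15 ± 0.36), the interferon-induced Ifitm3 (1.79 ± 0.36), Samd12 (1.66 ± 0.29), Espn (1.81 ± 0.33), the cytochrome Cyp1b1 (at least 6.10-fold), Cnksr1 (at least 5.64-fold) and Castor1 (at least 2.71-fold). On the lower side stood Cpne6 (at least 5.16-fold), Gpr85 (at least 4.10-fold), Tmx4 (at least 4.08-fold), the sarcomere genes Myoz2 (at least 3.70-fold) and Myh15 (at least 2.50-fold), Me3 (at least 2.30-fold), Ovol3 (at least 1.94-fold), Ppm1k (at least 1.40-fold) and Porcn, which acylates Wnt proteins (-1.35 ± 0.24). Of these lower genes, Porcn was the one well above background in mutants, whose paraxial arrays had fewer probes well above background than the wild-type ones. Without mutant paraxial array 1, 16 genes passed, and without wild-type paraxial array 2, 7 did.

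**Figure D2:**
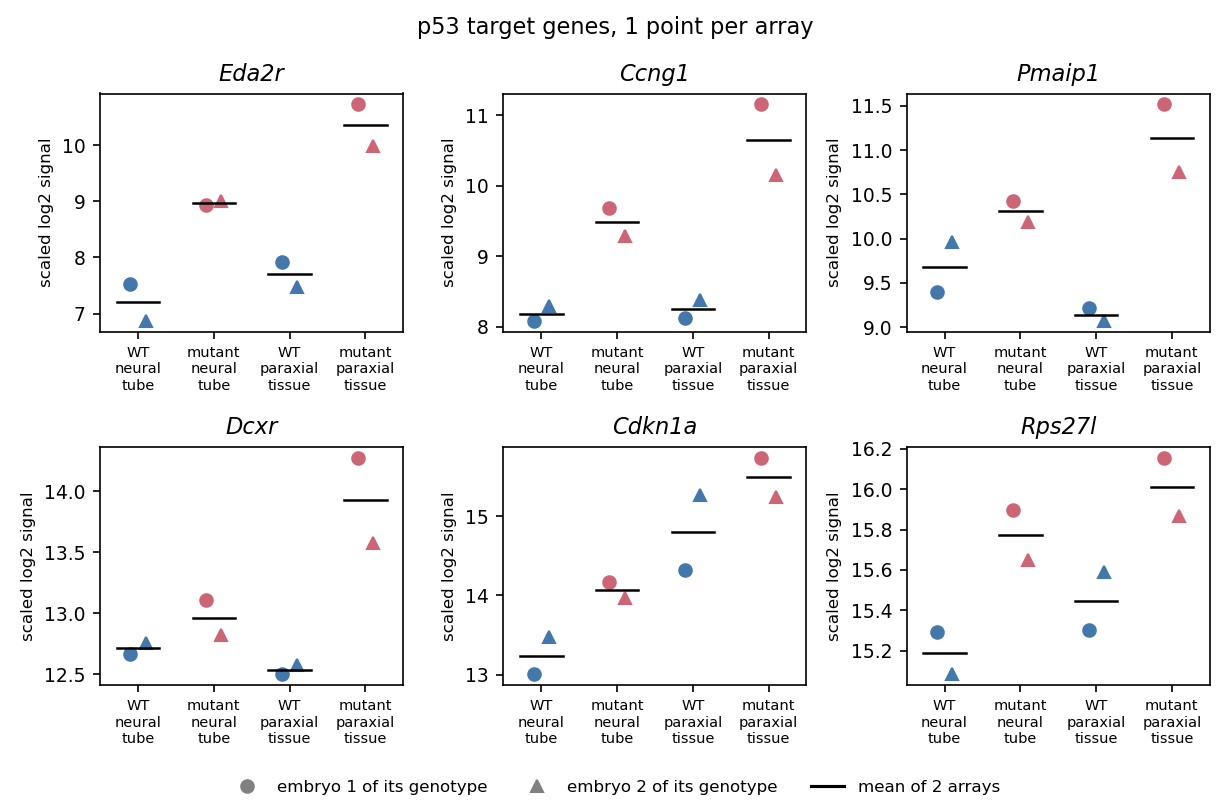
Scaled log2 signal of 6 p53 target genes on each of the 8 arrays (points), by group, with the mean of the 2 arrays as a bar and embryo 1 and 2 of each genotype as circles and triangles. Eda2r averages 7.20 and 8.97 in wild-type and mutant neural tube, and 7.70 and 10.35 in wild-type and mutant paraxial tissue.

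In neural tube the p53 target list was higher in mutants as well (29 of 36, median 0.35; camera adjusted p = 1.73e-05, and 0.0163 with an estimated correlation), the single list of 36 that passed both ways. Eda2r stood at 1.77 ± 0.38, Ccng1 at 1.30 ± 0.36, the cyclin-dependent kinase inhibitor Cdkn1a (p21) at 0.83 ± 0.36 and Rps27l at 0.59 ± 0.27, and 0 members passed over all genes or the list alone. The call was lost (adjusted p = 0.267) without both arrays of wild-type embryo 1, and by fry (adjusted p = 0.168). Markers of surface ectoderm moved with the p53 list here too, with a mean of 0.09 and -0.16 on the mutant and -0.48 and -0.31 on the wild-type neural tube arrays (camera adjusted p = 0.0227, but adjusted p = 0.274 with an estimated correlation). Genes of replication licensing and origin firing, the process that Geminin restrains, lay higher in mutant neural tube (39 of 42, median 0.47; camera adjusted p = 5.14e-10), a call lost at adjusted p = 0.186 with an estimated correlation. Orc2 stood at 0.87 ± 0.25, the origin recognition subunit Orc1 at 1.04 ± 0.37, Gins2 at 0.90 ± 0.31 and Mcm10 at 0.74 ± 0.30, and 0 members passed. Without both arrays of mutant embryo 1 the licensing call was lost (adjusted p = 0.107, median 0.17). The list mean was 0.45 on mutant neural tube 1 and -0.07 on mutant neural tube 2. In paraxial tissue the same list had 38 of 42 members higher (median 0.28; camera adjusted p = 1.00e-04, but adjusted p = 0.445 with an estimated correlation). That call was also lost without wild-type embryo 1 (adjusted p = 0.203) or mutant embryo 1 (0.128).

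Posterior Hox genes, which mark the level along the body axis, lay lower in mutant neural tube, with the lowest values in mutant embryo 1. Hox paralogs 6 to 9 had 11 of 12 members lower (median -0.91; camera adjusted p = 0.00103, but adjusted p = 0.347 with an estimated correlation) and Hox paralogs 10 to 13 had 9 of 9 lower (median -2.30; camera adjusted p = 4.24e-05, but adjusted p = 0.201 with an estimated correlation). Hoxa9 stood at -1.86 ± 0.67, Hoxd9 at -2.04 ± 0.81 and Hoxa10 at -2.30 ± 0.83, and 0 members passed. Without both arrays of mutant embryo 1 the medians were 0.02 (adjusted p = 0.618) and -0.39 (adjusted p = 0.103), and without both arrays of wild-type embryo 2 the adjusted p was 0.341 and 0.113. For paralogs 6 to 9 it was 0.0835 without mutant neural tube 1 and 0.0678 without wild-type neural tube 2. Differentiated neuron genes lay lower in mutant neural tube (26 of 30, median -0.45; camera adjusted p = 0.00496, but adjusted p = 0.683 with an estimated correlation), led by Robo3, a receptor of commissural axons (-2.46 ± 1.29). The adjusted p of the neuron list was 0.912 without mutant neural tube 1 and 0.270 without wild-type neural tube 2.

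Lists of chromatin complexes that Geminin is known to contact did not pass the test. Of 36 Polycomb and Trithorax genes, 20 lay higher in mutant neural tube (median 0.05; camera adjusted p = 0.262) and 15 in mutant paraxial tissue (median -0.07; camera adjusted p = 0.791). Of 26 SWI/SNF (BAF) genes, 12 lay higher in neural tube (median -0.10, mean -0.32; camera adjusted p = 0.498) and 15 in paraxial tissue (camera adjusted p = 0.603). The SWI/SNF list means in neural tube were -0.30 and -0.02 on the mutant and 0.19 and 0.14 on the wild-type arrays. In paraxial tissue the SWI/SNF median was 0.06, but the mean was -0.17 and the test pointed down. Planar cell polarity and neural tube closure genes had 23 of 35 members higher in mutant neural tube (median 0.20), with a camera adjusted p of 0.0536 at the preset correlation and 0.0453 with an estimated one.

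No single gene passed in neural tube either. limma called 0 of 28940 genes, with 1050 at an unadjusted p under 0.05, fewer than the 1447 expected by chance. It called 0 with trend and robust moderation (1076 unadjusted) and 0 without an embryo block (1469). On the higher side, among the genes with the smallest p, stood Cyp26b1 at 2.83 ± 0.43 (adjusted p = 0.583), Crtap (0.99 ± 0.23), Pter (1.19 ± 0.27), Slc20a2 (1.18 ± 0.28), Ddx20 (1.25 ± 0.30), Mlec (1.32 ± 0.32), Poglut3 (1.36 ± 0.33) and Tmem64 (1.08 ± 0.27). All 10 genes with the smallest p on the lower side were not well above background in mutant neural tube. Among them were the lysosomal protease Ctss (at least 3.17-fold), Myo3b (at least 2.57-fold), Nlrp10 (at least 2.05-fold), Ppm1k (at least 1.57-fold) and Prok1 (at least 1.54-fold). The mutant neural tube arrays also had fewer probes well above background than the wild-type ones. In simulated arrays of the same 28940 genes, 38% of genes changed by 2 on the log2 scale and 88% of those changed by 3 were recovered in this comparison. The simulated genes were independent and carried no effect of slide row or brightness, so recovery on the real arrays could be lower.

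**Figure D3:**
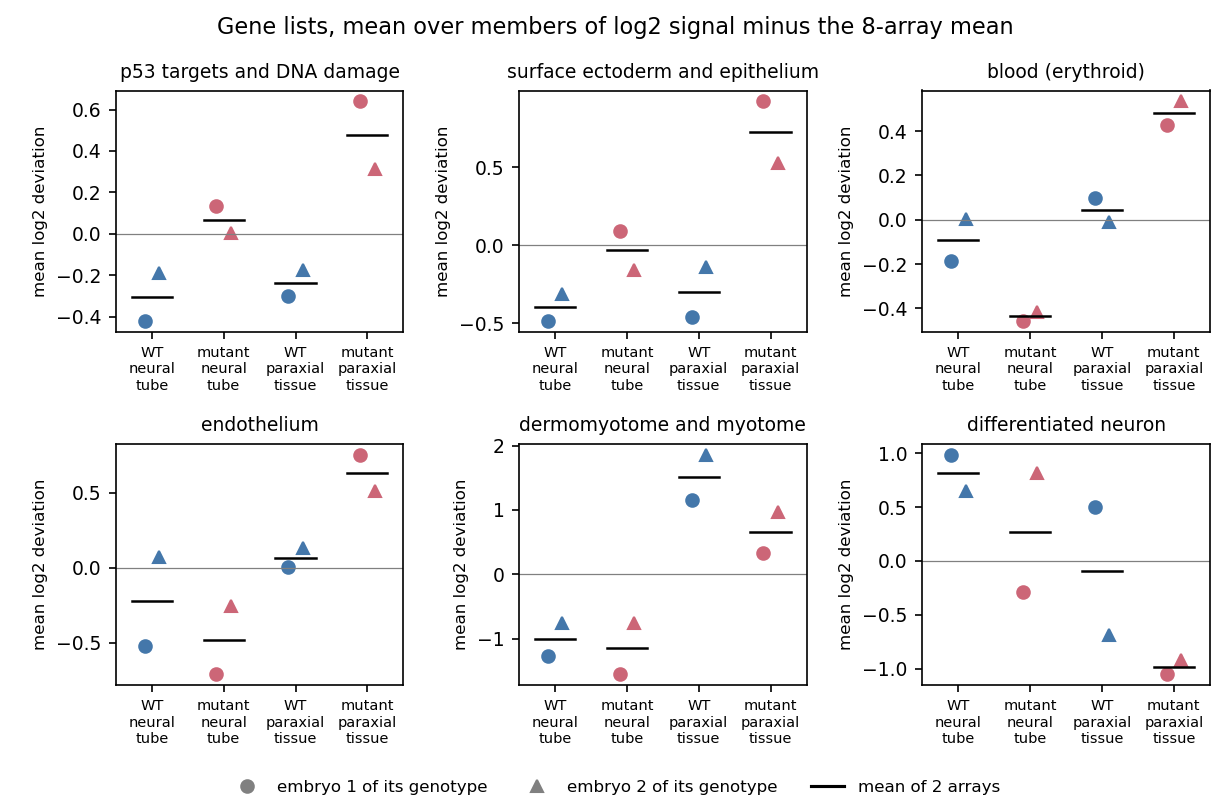
Mean log2 deviation of 6 gene lists from their own mean over 8 arrays, for each array (points) by group, with the mean of the 2 arrays as a bar. The p53 target list stands at 0.64 and 0.31 in mutant paraxial tissue and at 0.13 and 0.00 in mutant neural tube, above both wild-type arrays of each tissue.

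Averaged over both tissues, limma called 0 genes between genotypes (850 at an unadjusted p under 0.05, against 1447 expected by chance). It called 0 with trend and robust moderation (868 unadjusted) and 0 without an embryo block (2751 unadjusted). Lists that were higher in mutants both with the preset and with an estimated correlation were p53 targets (median 0.49; camera adjusted p = 7.27e-13), surface ectoderm (0.57; 5.97e-09), gut and notochord (0.60; 0.00496), the retinoic acid pathway (0.10; 0.00700) and BMP and TGF-beta targets (0.37; 0.0227). Genotype changes in the 2 tissues correlated across genes at r = 0.519, which describes genes of the same 4 embryos and not independent replicates. The same r was 0.613 when the embryos were split by replicate number and 0.531 for the remaining split into 2 and 2. Fold changes ran with brightness: from the dimmest to the brightest eighth of genes the median went from -0.32 to 0.22 in neural tube and from -0.17 to 0.23 in paraxial tissue.

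Embryos of 1 genotype also differed from each other. A split of the embryos by replicate number, which is also the row of the slide, called 445 genes in neural tube and 226 in paraxial tissue, where genotype called 0 and 0. At the preset correlation camera also called 9 and 8 lists in that split and 13 and 11 in the remaining one, against 13 and 15 for genotype; with an estimated correlation the counts were 2 and 2, 0 and 1, and 2 and 6. The p53 list was called in the remaining split of paraxial tissue at the preset correlation (adjusted p = 0.0238), but at adjusted p = 0.814 with an estimated correlation. Transcripts of the Y-linked genes Ddx3y, Kdm5d and Uty were well above background on both arrays of mutant embryo 2 and on no other array, while the probe of Eif2s3y, also Y-linked, was well above background on all 8 (10.4 or above). Xist, which is transcribed from the inactive X chromosome, stood at 7.25 or below in that embryo and at 13.9 to 14.8 on the other arrays. By these transcripts mutant embryo 2 was male and the other embryos female, so sex was not balanced between the genotypes.

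By camera, the genotype change differed between the tissues for 5 lists, with both the preset and an estimated correlation. In the same test genotype had 12 lists at the preset correlation and 5 with an estimated one. The split by replicate number had 14 and 9, and the remaining split 3 and 0. The 9 were other lists than these 5, but such calls are not particular to genotype. Among the 9 were markers of both tissues, such as neural progenitor, ventral neural tube and sclerotome genes. The tissue difference of these markers thus varied with replicate number, and the cause was not tested. Erythroid genes had genotype medians of opposite sign, -0.26 in neural tube and 0.53 in paraxial tissue (difference -0.69; camera adjusted p = 4.09e-13), and 7 of 17 members differed when adjusted over the list alone, among them Alas2 (-1.03 ± 0.20), Slc4a1 (-1.25 ± 0.25) and Klf1 (-1.03 ± 0.25). The erythroid list in neural tube had a camera adjusted p = 0.0423, but adjusted p = 0.0817 with an estimated correlation, and passed in 5 of 12 fits that left out an array or embryo, with medians from -0.26 to -0.09. Endothelial genes had medians of -0.19 and 0.63 (difference -0.82, camera adjusted p = 2.76e-12). Over the left-out fits this difference ran from -1.24 to -0.45. The -0.19 in neural tube was 0.11 without mutant neural tube 1, 0.07 without wild-type neural tube 2, 0.04 without mutant embryo 1 and 0.13 without wild-type embryo 2. Surface ectoderm genes had medians of 0.31 and 0.97 (difference -0.61; adjusted p = 8.25e-08), led by Cldn3 (-2.26 ± 0.59) and Cldn4 (-1.37 ± 0.43). BMP targets (adjusted p = 0.00480) and gut and notochord genes (adjusted p = 0.00754) completed the 5. For p53 targets the difference between tissues was lost with an estimated correlation (camera adjusted p = 3.90e-04, but adjusted p = 0.0575 with an estimated correlation). At the level of genes limma called 0, with 1495 at an unadjusted p under 0.05 against 1447 expected by chance. The smallest limma adjusted p was 0.0929, and limma also called 0 with trend and robust moderation. It called 4 after cyclic loess, among them Myh15 and Ccdc187. It called 19 without mutant paraxial tissue 1, 15 without wild-type paraxial tissue 2, among them Cpne6 (adjusted p = 0.0188), and 6 without mutant embryo 1. The genes picked by smallest p, among them Cpne6, Myoz2, Myh15 and S1pr5 (adjusted p = 0.273 each), were not well above background in at least 1 of the 4 groups, so no size of the difference is given. The interaction for BMP targets was lost without wild-type neural tube 2 (adjusted p = 0.243), wild-type paraxial tissue 2 (0.0943) or mutant paraxial tissue 1 (0.0534), and that for gut and notochord genes without wild-type neural tube 2 (0.482) or with normexp background correction (0.0530). Without both arrays of wild-type embryo 2 the BMP interaction had an adjusted p of 0.188, and without those of mutant embryo 1 the gut and notochord interaction one of 0.0743.

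**Figure D4:**
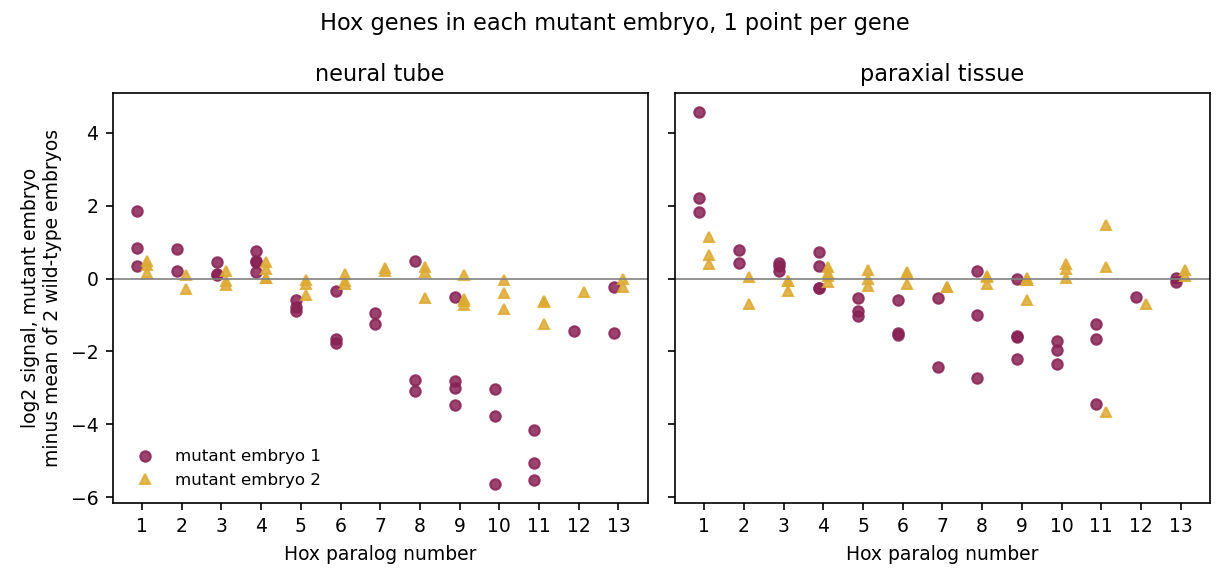
Log2 signal of each measured Hox gene in mutant embryo 1 (circles) and mutant embryo 2 (triangles) minus the mean of the 2 wild-type embryos, by paralog number, in neural tube and paraxial tissue. For paralogs 6 to 13 the median is -2.78 and -1.54 in mutant embryo 1 and -0.24 and 0.02 in mutant embryo 2.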

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

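All tests of explanations in this part were chosen after the result was seen. By a test of the interaction, camera called 12 gene lists as differing in genotype change between the tissues at the preset correlation. With an estimated correlation 5 of them were also called, and these 5 are given here with the preset adjusted p. The split of the embryos by replicate number had 14 and 9 lists in the same test, so such calls are not particular to genotype. Erythroid genes (adjusted p = 4.09e-13) had medians of opposite sign in the tissues, although the neural tube call had adjusted p = 0.0817 with an estimated correlation and passed in 5 of 12 left-out fits. So had endothelial genes (2.76e-12), whose neural tube median of -0.19 was 0.11 without mutant neural tube 1 and 0.07 without wild-type neural tube 2 and whose neural tube call had adjusted p = 0.683 with an estimated correlation. Surface ectoderm genes (8.25e-08), BMP and TGF-beta targets (0.00480) and gut and notochord genes (0.00754) had a larger genotype change in paraxial tissue than in neural tube. The erythroid, endothelial and surface ectoderm interactions passed in all 12 fits that left out an array or an embryo. By fry the interaction was lost for endothelial genes (adjusted p = 0.144, and 0.0449 by camera with an estimated correlation), gut and notochord genes (0.0982) and BMP targets (0.0806).

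The higher surface ectoderm and epithelium list in mutant paraxial tissue could come from fold changes that run with brightness or from the genotype. It could also come from surface ectoderm or another epithelium captured with the tissue. The gut and notochord list was higher in this tissue too, so the list does not tell which epithelium. After cyclic loess, which takes out most of the trend with brightness, the adjusted p with an estimated correlation was 8.75e-06, which excludes the trend as the whole cause. All 5 of the brightest members were higher in both mutant than in both wild-type paraxial arrays. Nearly all members of the list were already known to lie higher. Captured epithelium and a change of expression would both give this, so it decides nothing. Log2 changes were 0.26 for Trp63, 2.13 for Krt18, 1.67 for Cldn4, 0.73 for Esrp1 and 0.78 for Krt7. That of Trp63, the brightest, was close to the median of 0.23 in the brightest eighth of genes. In neural tube the list had an adjusted p of 0.274 with an estimated correlation, which leaves a change in every tissue open. Sections stained for Krt8 or Epcam beside the captured area could separate capture from expression.

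The higher p53 target list in mutant paraxial tissue could come from the trend with brightness, from differences between embryos other than genotype, or from genotype. After cyclic loess the adjusted p was 5.41e-06 with an estimated correlation, which excludes the trend as the whole cause. In the other 2 splits of the embryos the smallest adjusted p over both tissues was 0.814 with an estimated correlation, which with 2 embryos per genotype does not exclude embryo differences. All 4 mutant arrays had a list mean above both wild-type arrays of their tissue, which differences between embryos would give as well, so genotype stays open. Eda2r, Ccng1 and Cdkn1a in further embryos could test it.

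A signal was also present in spots that no comparison used: on each array at least 27.8% of ERCC spike-in control spots were well above background, against at most 1.62% of negative control spots, and the protocols name no spike-in.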

How the results depend on the processing

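No test in this part was chosen after the result was seen, except cyclic loess, left-out embryos for gene lists and the other splits. Named genes of the tissue differences were weaker in 321 of 1116 checks in wild type and in 224 of 736 in mutants. Named genes of the genotype and interaction contrasts had not passed to begin with, so that an unchanged side of the threshold (1001 of 1001 checks in neural tube, 1359 of 1361 in paraxial tissue, 454 of 458 for the interaction) shows no stability. Gene lists kept their direction and side in 1306 checks, were weaker in 233 and reversed in 15. With 2 embryos per genotype and a median signal of 2.11 to 3.16 times that of negative controls, small changes and dim genes could be missed. Where not stated otherwise, the cause was not tested.

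At a fold of 2 and an unadjusted p under 0.05 the counts were 474 (genotype in neural tube), 564 (in paraxial tissue), 367 (averaged), 673 (interaction), 1931 (tissue in wild type) and 2110 (tissue averaged), a looser or different threshold by construction. Cyclic loess gave 4 genes for the interaction. For tissue in wild type normexp gave 1491 genes, no filter 362, trend and robust moderation 1089, array weights 402 and its 4 arrays alone 181. For tissue in mutants no filter gave 610 and its 4 arrays alone 1102, and for averaged tissue no filter gave 2298. The correlation of genotype effects between tissues was 0.457 without a filter and 0.613 for the split by replicate number.

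The embryo block rests on both tissues coming from the same embryo. Without a replicate block the tissue counts were 4 (wild type), 0 (mutant) and 593 (averaged), and with the embryo as a fixed block 51, 211 and 1973. Replicate numbers of wild-type and mutant embryos share only a number and the row of the slide, and same-numbered arrays of the 2 genotypes deviated together at r = 0.291 in both tissues; the second principal component separated replicate 1 (-69.1 to -17.9) from replicate 2 (33.6 to 61.1). With the replicate number as a block the tissue counts were 109, 69 and 1157, the genotype counts stayed at 0, with 2279 (neural tube), 1743 (paraxial tissue) and 3859 (averaged) genes at an unadjusted p under 0.05 against 1050, 971 and 850 in the embryo block and 1447 expected by chance, and the p53 list kept its call in both tissues (adjusted p = 9.79e-15 in paraxial tissue).

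Lists past the threshold went from 13 to 2 in neural tube, from 15 to 6 in paraxial tissue, from 12 to 5 for the interaction and from 19 to 11 for tissue in mutants with an estimated correlation, and to 0, 5 and 2 with fry for the first 3. Leaving out an array or embryo, where a lone array is assumed to vary like the other groups, gave 0 to 16 genes for genotype in paraxial tissue, 0 to 19 for the interaction, 31 to 586 for tissue in wild type, 0 to 1589 in mutants and 794 to 3497 averaged, and 2 to 21 lists for genotype in neural tube.

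Reversed were Olfr1204 for the interaction with normexp (0.0129), Icos in paraxial tissue without a filter (0.256) and the median of gut and notochord genes for tissue in wild type with normexp (-0.0546). List medians that changed sign when an array or embryo was left out ranged, for genotype in neural tube, from -0.985 to 0.00158 (differentiated neuron), -1.33 to 0.0986 (spinal neuron identity), -0.501 to 0.126 (endothelium) and -1.72 to 0.0212 (Hox 6 to 9). The range was -0.0238 to 0.467 for extracellular matrix in paraxial tissue, and for the interaction -0.0766 to 0.939 (differentiated neuron) and -0.0503 to 0.250 (licensing).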

Other observations

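The tests of explanations in this part were chosen after the result was seen, except the splits of the 8 arrays for the tissue difference. Ribosomal protein genes lay higher in mutants (43 of 44 in each tissue; camera adjusted p = 2.09e-05 in neural tube and 2.30e-09 in paraxial tissue), with adjusted p = 0.570 and adjusted p = 0.360 with an estimated correlation. In neural tube the median of 0.27 was 0.02 after cyclic loess (adjusted p = 0.457) and 0.08 after quantile scaling (adjusted p = 0.207). In paraxial tissue the list passed at the preset correlation in 7 of 7 alternatives of scaling, background, value table and block, with medians from 0.14 to 0.49. Wnt targets lay higher in mutant paraxial tissue (18 of 21; camera adjusted p = 3.00e-05, and adjusted p = 0.0530 with an estimated correlation). Macrophage and white blood cell genes lay lower in mutant neural tube (16 of 19; camera adjusted p = 0.00581, and adjusted p = 0.299 with an estimated correlation).

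The lower posterior Hox genes in mutants could come from genotype, from a more rostral level captured in mutant embryo 1, or from the row of the slide. In mutant embryo 2 the median of the 21 genes of paralogs 6 to 13 relative to both wild-type embryos was -0.24 in neural tube and 0.02 in paraxial tissue, and relative to the wild-type embryo in the same row of the slide -0.75 and -0.10 (mutant embryo 1: -2.12 and -1.15), which leaves genotype open. In mutant embryo 1 the deviation from the mean of all other embryos fell with paralog number, as a more rostral level would give. Spearman rho was -0.79 in neural tube and -0.68 in paraxial tissue. The permutation p was 1e-05, the smallest possible, and 3e-05, over genes that are not independent replicates. But rho was also -0.56 in neural tube of mutant embryo 2 (-0.04 in paraxial tissue), taken relative to the wild-type embryos alone. Wild-type embryo 1 had a median of -0.72 in neural tube and -0.37 in paraxial tissue relative to wild-type embryo 2, which neither excludes the row nor shows it in both tissues. The level of the sections in each embryo could settle it.

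In all 35 splits of the 8 arrays into 4 and 4, only 1 of 35, the tissue split itself, reached its count of 3376 genes (a model with tissue and genotype terms, against 3459 in the 4-group model), and the highest other was 1040, for replicate number. Only 8 of the splits part both tissues of every embryo as the tissue split does, too few for a share under 0.05, and the highest other among these was 0. Of the remaining splits, 24 part 2 of the 4 embryos and 3 part none. For the averaged genotype effect 35 of 35 splits had as many genes as its count of 0, an outcome that the count fixes, and the highest other was 3914, for the tissue split.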
